A study of Drosophila melanogaster with 3 samples.

How the data were processed

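RNA was measured in brains dissected from last instar larvae of Drosophila melanogaster of 3 genotypes, with 1 library for each genotype. The library labelled control came from animals with 1 copy of the dBRWD3 allele PX2 over a wild-type chromosome (dBRWD3PX2/+). The library labelled single mutant came from animals with the allele on both chromosomes (dBRWD3PX2/PX2), and the library labelled double mutant from animals that in addition carried the yem insertion GS21861 on both chromosomes (yemGS21861/GS21861). Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I, depleted of ribosomal RNA with a Ribo-Zero kit and made into libraries with the Ion Total RNA-Seq kit. Such libraries keep both messenger RNA and other RNA that is not ribosomal.

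The submitters' processing notes name FastQC, Trimmomatic, TopHat2 2.0.9 and Cufflinks 2.0.2, and the genome build dm3. Their settings and the strand handling are not given in the sources used here. The authors deposited 1 table with a row per assembled locus, a gene name, a position and an RPKM value (reads scaled to transcript length and to library size) for each library. All positions printed are those of the deposited table, in dm3. The annotation used here for transcript lengths, older gene symbols and host genes of small RNAs belongs to a later build (BDGP6), and none of its coordinates were printed or set against those of the table.

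The table held 15229 rows. Of these, 1769 (11.6%) named no gene and were left out of all comparisons except 1 alternative, and 1 row had a missing value. When several rows carried the same name, the row with the highest mean was kept, which dropped 101 rows and left 13358 genes. Of these, 522 were rows in which the authors' assembly joined several genes under 1 value, written here with their names joined by commas as in the table, so the values of those genes cannot be separated. Summed RPKM was very large (3.84e+07 in control, 4.08e+07 in the single mutant and 3.37e+07 in the double mutant library), because short noncoding RNAs and their host genes were given very large values. Ratios for small RNAs, their host genes and near-identical gene copies (such as Hsp70, Stellate and trypsin genes) are uncertain.

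In the control column, 7306 of 14316 values above 0 (51.0%) were written with more than 6 digits, and 98.5% of these ended in 5. No value in either mutant column had more than 6 digits. Averages of 2 values written with 6 digits would look like this, but the labels list 1 control library and no source used here states an average, so the control values are used as deposited and the number of preparations behind them is an open limit. RPKM values carry no direct read numbers. As an approximation, the most frequent lowest product of RPKM and transcript length (kb), in genes with 1 annotated transcript longer than 1 kb, lay between 0.03 and 0.04 in the control and double mutant libraries and between 0.04 and 0.05 in the single mutant library. If this step is 1 read, the libraries held about 2.9e+07, 2.9e+07 and 2.2e+07 reads, so that 1 RPKM over 1 kb rests on about 29, 29 and 22 reads. For control the figure would not hold if its column is an average.

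From the deposited RPKM values, ratios were computed as log2((a + 1)/(b + 1)), with a pseudocount of 1 RPKM, for 9693 genes with at least 1 RPKM in at least 1 of the 3 libraries. The pseudocount makes ratios of genes with low values smaller than their RPKM folds. A gene was counted as higher or lower at a ratio of at least 2-fold. A library stood apart for a gene when it differed by at least 2-fold from both others in the same direction while the others lay within 1.5-fold of each other. With 1 library per genotype there is no spread between replicates, no test was run and no p-value is given for any difference. Every statement compares these libraries, not the genotypes they are labelled with.

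Because any pair of the 3 comparisons shares a library, noise alone correlates them. Each gene's 3 log2 values, centred on the library medians, were shuffled among the libraries 1000 times. The mean and the central 95% of the shuffles are printed beside the observed values as the level with no special library. The shuffles reuse the observed values, so they hold real differences as well as noise and are not a level of noise alone. The observed values were not centred, so their counts by direction are not on quite the same footing as the shuffled ones. The median log2 ratios were 0.04 (single mutant to control), 0.04 (double to single mutant) and 0.07 (double mutant to control). The shuffling takes the 3 libraries as equally noisy, which may not hold if the control column is an average or because the single mutant library had fewer reads, and it was not tested. For gene lists, the median log2 ratio was placed among 10000 random lists of the same size, drawn from 20 classes of mean expression, as a description of these libraries and not as a test. A list was said to lie outside the random range below percentile 2.5 or above percentile 97.5, and lists with under 3 measured members were given no percentile. With independent members, 1.9 of 38 lists per comparison would lie outside on average. Random lists draw their members independently, whereas members of a real list can vary together or share reads. Real lists may therefore lie outside more readily than their percentiles imply. Shares have exact Clopper-Pearson 95% intervals, which treat genes as independent and cover counting error only. The calculation was tested on simulated data for the comparison of the dBRWD3 mutant with control. Of 200 genes out of 9693 that were changed in the middle library alone, 91.0% were recovered at 2.5-fold and 100% at 4-fold, with 0 other genes called. Only genes with a mean above 5 RPKM were changed, and the simulated noise was well below the spread of the ratios here. Their standard deviations were 0.59, 0.56 and 0.49 (single mutant with control, double with single mutant, double mutant with control). The simulation therefore checks the calculation and gives no rate of false calls in these data. In the run at 2.5-fold, however, a list of unchanged genes reached percentile 97.8, just outside the random range, so single lists near its ends are weak calls (the 4-fold run gave 46.0).

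Gene lists and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest positive and the 12 with the largest negative ratio between the single mutant and control libraries, 10 and 10 between the double and single mutant libraries, and 6 and 6 between the double mutant and control libraries. It left out mitochondrial genome, histone, rRNA, tRNA, snRNA, snoRNA and microRNA genes. It always named BRWD3, yem, w, Hira, His3.3A and His3.3B, and up to 4 members of each described list with the largest ratio in the comparison at hand. Any other gene named was chosen after its values were seen. The alternatives were pseudocounts of 0.1 and 5 RPKM, no filter and a filter at 5 RPKM, median-of-ratios scaling, upper-quartile scaling, leaving out short and multicopy RNA genes with rescaling to the same total, thresholds of 1.5-fold and 4-fold, and another definition of a return to control. The rescaling kept host genes of small RNAs in its total. Added after seeing the data were inclusion of rows with no gene name, exclusion of rows that join genes, of small RNA host genes, and of members of the lists for other tissues and cuticle, and a correction for transcript length (lowess on log10 length, fraction 0.3, for the 9064 genes, 93.5%, with a length). Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.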

Results

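Brain RNA of last instar Drosophila larvae was measured by total RNA sequencing in 3 libraries, 1 each for animals heterozygous for the dBRWD3 allele PX2 (control), homozygous for it (single mutant) and homozygous for it together with the yem insertion GS21861 (double mutant). BRWD3 encodes a WD-repeat and bromodomain protein. The yem product, yemanuclein, works with HIRA in placing the histone variant H3.3 into chromatin. The genotypes set PX2 homozygotes beside heterozygotes, and let the values with the added yem insertion be placed nearer to either. Values are RPKM as deposited, and 9693 genes reached 1 RPKM in at least 1 library. The labels list no replicates, so no difference could be set against a spread between samples. Every value is taken from 1 deposited column per genotype, and the control column may hold averages of more than 1 value.

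The targeted genes did not tell the libraries apart at the RNA level. BRWD3 (3R, 20144740 to 20159036) had 29.1 RPKM in control, 43.2 in the single mutant and 47.8 in the double mutant, so its RNA was 1.48-fold higher in the single mutant than in control. The yem gene, listed under its older symbol yemalpha (3R, 24942112 to 24948597), had 11.9, 8.04 and 15.6 RPKM, with the highest value in the library labelled as its mutant. What the alleles do to the RNA is not given in the sources used here, and these values therefore do not check the labels. The libraries are named below as they were labelled. The eye colour gene w, a copy of which often marks inserted elements, had 6.74 RPKM in control, 2.65 in the single mutant and 23.6 in the double mutant, 8.90-fold higher in the double than in the single mutant.

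Genes for H3.3 and its deposition differed little, with 1 exception. Hira, which encodes the H3.3 chaperone, had 8.76 RPKM in control, 2.80 in the library labelled single mutant (3.13-fold lower) and 9.48 in the library labelled double mutant. His3.3A, 1 of the H3.3 genes, had 530, 571 and 603 RPKM, and His3.3B had 322, 584 and 460 RPKM. Of the 15 measured genes for H3.3 deposition and histone chaperones, 14 lay within 2-fold between the single mutant and control libraries and 15 of 15 between the double mutant and control libraries. The list medians were -0.14 (percentile 3.04 among random lists) and -0.10 (percentile 9.27), inside the random range. The 6 measured genes of the cullin 4 ubiquitin ligase all lay within 2-fold in each comparison.

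Between the library labelled single mutant and control, digestive enzymes and storage proteins were among the lower genes. The glue genes Sgs5, Sgs7 and Sgs8 were higher, and most Notch target and ecdysone response genes were higher by less than 2-fold. In the single mutant library 262 genes were at least 2-fold higher and 349 at least 2-fold lower than in control. The excess of lower genes turned at 1.5-fold (1034 higher and 917 lower) and was larger with rows of no gene name (444 and 806). The serine protease Jon65Aiii had 29.9 RPKM in control and 0.280 in the single mutant library, deltaTry had 25.1 and 0.589, yip7 had 10.3 and 0.0795, and Jon65Aiv had 9.74 and 0.177. The trypsin gene CG30031 had 21.8 and 0.474 RPKM and the joined row CG30025,alphaTry,gammaTry had 24.5 and 0.872. LysS, a lysozyme of the gut, had 13.6 RPKM in control and was listed at 0 in the single mutant library, as were CG12115 (8.63 RPKM in control) and Sfp33A4 (10.6). CG7916,CG7953 (31.9 and 0.909 RPKM), CG8664 (8.55 and 0.171) and the larval cuticle gene Lcp4 (73.7 and 8.77) completed the 12 lowest.

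Among the 12 genes highest in the library labelled single mutant relative to control, Arc1,CG10102, a row that holds the capsid-like gene Arc1, had 93.3 RPKM in control and 1000 in the single mutant. The odorant-binding protein gene Obp56d had 17.9 and 139 RPKM and the ionotropic receptor gene Ir40a had 0.102 and 13.4. The glue protein gene Sgs5 had 24.0 and 129 RPKM. CG33333 (3.36 and 33.6 RPKM), CG42834 (5.55 and 68.3) and CG14332 (5.14 and 30.7) are neighbours on 3R between 13243188 and 13247924. CG41503, on the unplaced Y heterochromatin sequence YHet, had 0.323 and 29.2 RPKM, CG30098 had 0.4998 and 10.6, CG5399 had 6.98 and 58.2 and CG33346 had 0.720 and 7.998. The largest log2 ratio, 6.81 with 1 RPKM added, belonged to cno,dpr16 (10.02 and 1236 RPKM), a row that joins genes and holds a small RNA gene, so its value cannot be given to either gene.

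Gut enzyme and fat body genes had the largest list medians between the libraries labelled single mutant and control, and other markers of non-brain tissue did not all go the same way. Of 10 measured gut enzyme genes, 5 were at least 2-fold lower in the single mutant library and the list median was -1.38 (percentile 0.01 among random lists). Over the 9 of them with a known transcript length the median was -0.57 (percentile 0.69). Of 10 fat body genes, 5 were at least 2-fold lower and 0 higher, with a median of -0.97, below all 10000 random lists. Fbp1 had 100.5 RPKM in control and 29.5 in the single mutant library, the storage protein gene Lsp2 had 271 and 82.5, Lsp1gamma had 34.7 and 15.8 and Lsp1beta had 64.3 and 29.9. Of 15 hemocyte and basement membrane genes, 1 was at least 2-fold higher and the median was 0.49 (percentile 99.9). That gene was the scavenger receptor crq (9.97 and 24.5 RPKM). Of 10 salivary gland genes, 4 were at least 2-fold higher, with a median of 0.39 (percentile 98.4). These were Sgs5, Sgs8 (44.3 and 184 RPKM), Sgs7 (84.0 and 317) and CrebA (1.05 and 3.13), and the list median lay inside the random range with no filter and with a pseudocount of 5 RPKM but was 0.89 over the 9 members with a known length. Sgs3, another glue gene, was lower (6.89 and 5.40 RPKM). The ring gland, muscle, eye disc, imaginal disc and germline lists lay inside the random range.

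Within the brain lists, genes for transmitters and neuropeptides stood low in the library labelled single mutant. Of 28 such genes 23 were lower than in control, 3 of them at least 2-fold, and the median of -0.43 lay below all 10000 random lists. The neuropeptide genes hug (20.9 RPKM in control and 8.08 in the single mutant library), npf (20.3 and 8.35) and Dsk (12.5 and 5.68) had the largest ratios, and eclosion hormone, Eh, had 3.43 and 1.26. The neuroblast, neuronal function, learning and memory and glial lists had medians of 0.22, 0.07, -0.15 and 0.08, all inside the random range. Cell cycle and DNA replication genes had a median of -0.15 (percentile 0.23), although 29 of 29 lay within 2-fold. The replication genes Orc1 (14.02 and 7.24 RPKM) and Mcm6 (107 and 69.2), the kinase gene aur (29.7 and 17.8) and the transcription factor gene E2f (13.5 and 24.2) had the largest ratios.

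Several response pathways stood high in the same library. Of 11 Notch target genes 9 were higher than in control, 1 at least 2-fold, with a median of 0.60 (percentile 99.96). HLHm3,HLHmgamma had 68.8 RPKM in control and 149 in the single mutant library, m2 had 171 and 274, HLHmbeta had 229 and 365 and malpha had 129.7 and 204. Of 21 ecdysone response genes 18 were higher, 2 at least 2-fold, with a median of 0.44 (percentile 99.98). ImpE3 had 10.9 and 31.2 RPKM, ImpE2 had 249 and 612, ImpE1 had 28.1 and 57.2 and Hr46, in the row CG12912,Hr46, had 0.573 and 2.09. Of 14 apoptosis and stress kinase genes 12 were higher, with a median of 0.43 (percentile 99.9). Xrp1 (23.9 and 48.0 RPKM), Ice (29.5 and 56.0) and Mmp1 (10.1 and 19.7) lay just under 2-fold with 1 RPKM added, whereas egr, the TNF ligand gene, had 21.8 and 4.38 RPKM.

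Of 15 antimicrobial peptide and immune genes 4 were at least 2-fold higher in the library labelled single mutant and 1 lower, with a median of 0.35 (percentile 99.5). CecA1 had 0.224 RPKM in control and 3.93 in the single mutant library, PGRP-SA had 2.84 and 7.89, the IM10 row CG33470,IM10 had 0.616 and 2.49 and Drs had 3.85 and 8.96. This list lay inside the random range with no filter and without rows that join genes. Its 14 members with a known transcript length lay inside it both before (percentile 96.6) and after correction for length (median 0.15, percentile 90.7). Of 15 glycolysis genes 9 were lower, with a median of -0.19 (percentile 1.40), and Pepck, of gluconeogenesis, had 5.91 and 1.69 RPKM. The kinase gene Pfk had 67.3 and 33.8 RPKM, Gapdh1 had 346 and 189 and PyK had 297 and 167. That median moved just inside the random range after correction for length (percentile 2.54) and with rows of no gene name included (percentile 2.84).

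**Figure D1:**
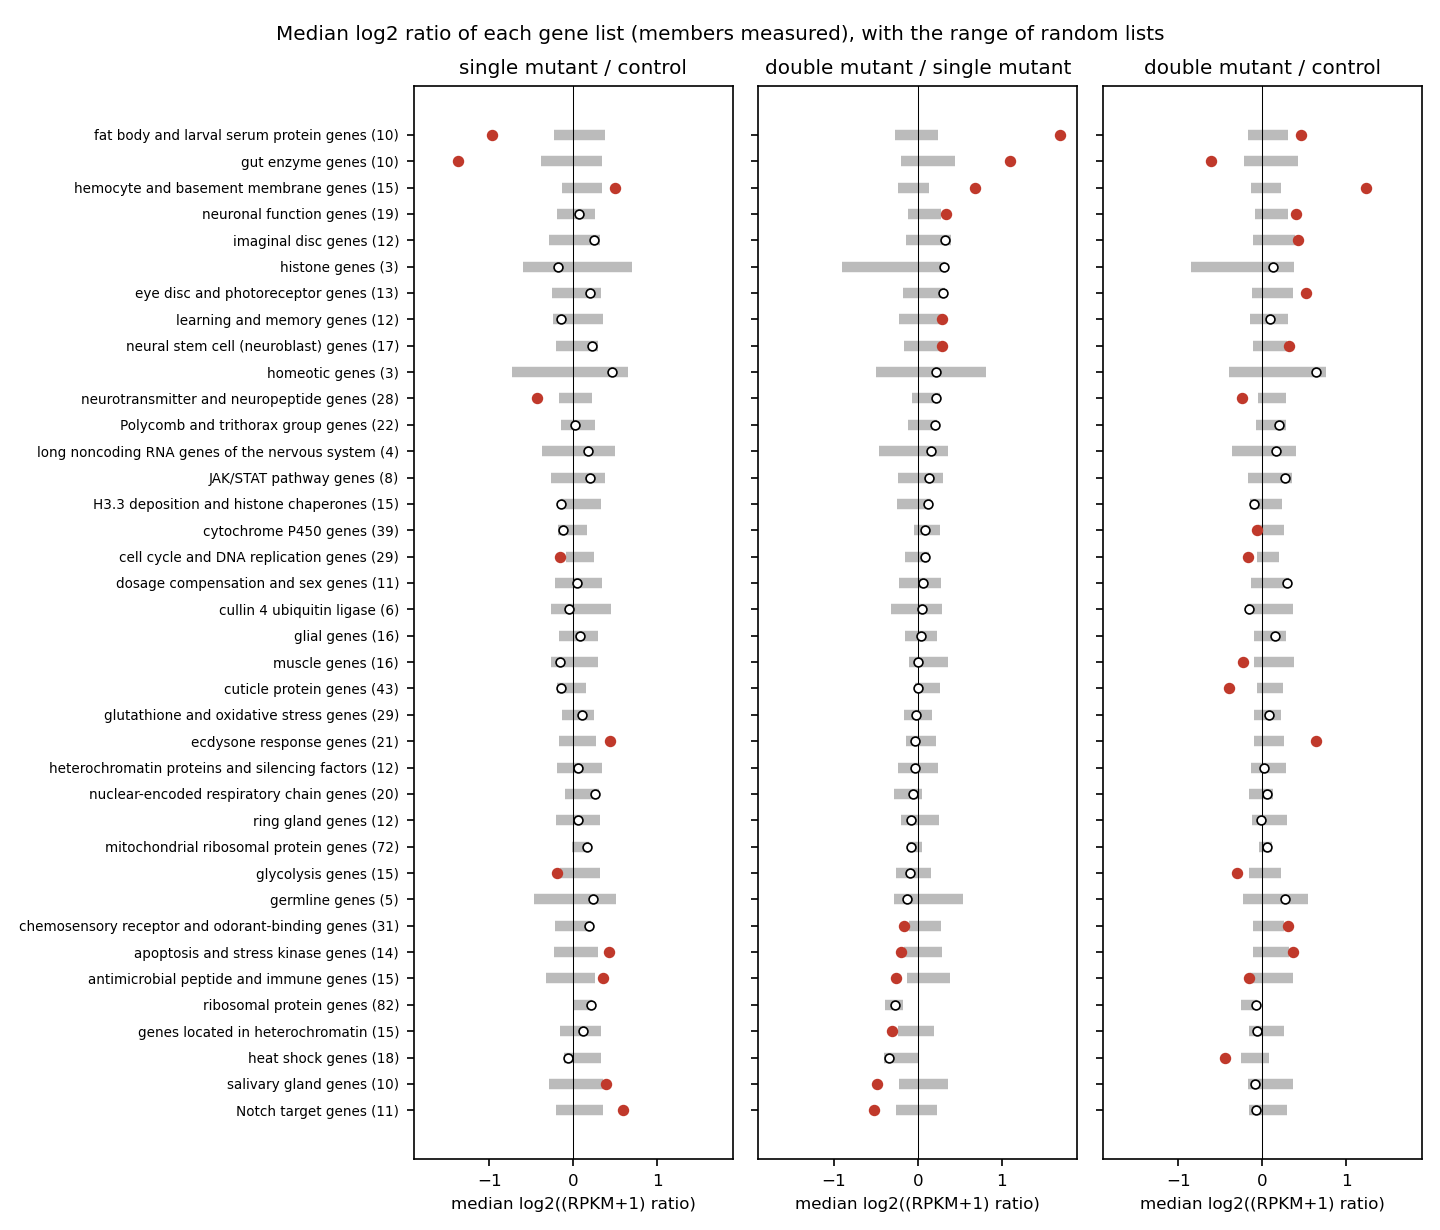
Median log2 ratio, with 1 RPKM added to each value, of each gene list in the 3 comparisons (x axis), with the number of measured members in brackets. Grey bars span the central 95% of 10000 random lists of the same size and expression, and filled points lie outside that range (11 of 38 lists in the left, 12 in the middle and 18 in the right panel). Fat body and gut lists sit far left in the left panel and far right in the middle panel.

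Between the libraries labelled double mutant and single mutant, storage proteins and several digestive enzymes were higher, and the glue genes Sgs5, Sgs7 and Sgs8 were lower. In the double mutant library 414 genes were at least 2-fold higher and 143 at least 2-fold lower than in the single mutant library. Leaving out short and multicopy RNA genes and rescaling the rest to the same total raised the double mutant values, with a median ratio of 0.28 in place of 0.04, and the counts became 636 higher and 64 lower. That total kept host genes of small RNAs, and the factors were 0.957, 0.937 and 1.13 for control, single and double mutant. With hosts left out too, summed RPKM was 1.38e+06, 1.60e+06 and 1.42e+06, so the double mutant sum was not below control. The rescaled counts may therefore rest on host rows, which was not tested. Lsp1alpha had 23.0 RPKM in the single mutant and 231 in the double mutant library, LysS was listed at 0 and had 8.77, and GalNAc-T2, a mucin-type glycosyltransferase gene, had 2.67 and 34.6. CG11697 (X, 11466739 to 11467673) had 0.0652 and 32.4 RPKM, the cytochrome P450 gene Cyp4p2 had 0.0871 and 10.5 and the new glue gene ng3 had 0.604 and 12.4. CG34166 (16.2 and 210.4 RPKM), CG15369 (0.221 and 13.7), CG18649 (0.333 and 13.3) and Acp98AB (listed at 0 and 7.54) completed the 10 highest.

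The 10 lowest genes in the library labelled double mutant relative to the single mutant included 3 glue genes, Sgs8 (184 RPKM in the single mutant and 21.0 in the double mutant library), Sgs5 (129 and 17.2) and Sgs7 (317 and 46.7). The joined row cno,dpr16 had 1236 and 5.83 RPKM. CG18607 had 28.7 and 0.0524 RPKM, and CG10474 (22.4), CG10476 (7.86) and CG42680 (10.4) were listed at 0 in the double mutant library. CG42807 (28.2 and 3.80 RPKM) and CG33346 (7.998 and 0.627) were the others. The glue protein genes and ng3, both known from salivary glands, went opposite ways. The salivary gland list had 3 of 10 members at least 2-fold higher and 4 at least 2-fold lower, with a median of -0.49 (percentile 0.02), which lay inside the random range with no filter.

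Of the 10 fat body genes 6 were at least 2-fold higher in the library labelled double mutant than in the single mutant, with a median of 1.70, above all 10000 random lists. Lsp1gamma had 15.8 and 123 RPKM, Lsp2 had 82.5 and 505 and Lsp1beta had 29.9 and 145, while Rfabg, the lipophorin gene, had 11.2 and 13.5. Of the 10 gut enzyme genes 5 were at least 2-fold higher, with a median of 1.09, above all random lists (0.58, percentile 99.0, over the 9 with a known length), as for Jon65Aiii (0.280 and 9.57 RPKM), deltaTry (0.589 and 8.96), CG30025,alphaTry,gammaTry (0.872 and 9.37) and Jon65Aiv (0.177 and 3.89). Of the 15 hemocyte and basement membrane genes 5 were at least 2-fold higher and 0 lower, with a median of 0.68, above all random lists. The prophenoloxidase genes CG8193 (43.6 and 214 RPKM) and proPO-A1 (92.0 and 365), the hemocyte gene Hml (29.4 and 94.1) and the blood cell factor gene srp (4.02 and 10.3) had the largest ratios.

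Notch target genes were lower in the library labelled double mutant than in the single mutant in 9 of 11 cases, with a median of -0.53 (percentile 0.01). m1 had 16.9 and 6.75 RPKM, HLHm3,HLHmgamma had 149 and 68.5, HLHm7 had 118 and 60.8 and m2 had 274 and 159. Antimicrobial and immune genes had a median of -0.26 (percentile 0.26), with 4 of 15 at least 2-fold lower, among them AttA (4.11 and 0.820 RPKM), CG33470,IM10 (2.49 and 0.380), AttB (7.72 and 2.63) and CecA1 (3.93 and 1.29). That list lay inside the random range after correction for length (percentile 30.3). The apoptosis and stress kinase list had a median of -0.20 (percentile 1.14), the list of genes in heterochromatin -0.31 (percentile 0.49) and the chemosensory list -0.17 (percentile 0.42). The apoptosis median turned to 0.03 under the rescaling without short RNA genes, and the chemosensory median to 0.13. The chemosensory list lay inside the random range there, with no filter (percentile 16.6) and with a filter at 5 RPKM (percentile 29.2). The insulin-like peptide genes Ilp2 (39.7 and 18.8 RPKM), Ilp3 (13.3 and 5.94) and Ilp5 (7.70 and 3.22) were lower, whereas Ilp7 had 0.919 and 2.58 RPKM.

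Genes of neural function stood higher in the library labelled double mutant than in the single mutant. The neuronal function list had 15 of 19 genes higher and a median of 0.33 (percentile 99.3), with brp (7.48 and 21.0 RPKM), Syt1 (2.09 and 4.92), para (1.02 and 2.16) and Sh (0.740 and 1.69) leading by ratio. The neuroblast list had 11 of 17 higher and a median of 0.29 (percentile 98.5), led by pros (9.99 and 22.1 RPKM), and the learning and memory list had 8 of 12 higher and a median of 0.29 (percentile 98.1), led by dnc (3.35 and 7.26). Longer transcripts had higher ratios across all genes in this comparison (Spearman 0.27 across 9064 genes, which are not independent replicates), with a median of 0.23 for transcripts of 4 kb or more and -0.11 for those under 1 kb. After correction for transcript length these 3 lists lay inside the random range, with medians of -0.05, 0.14 and 0.08. The 9 learning and memory genes with a known length already lay inside it before correction (percentile 94.3). The learning and neuroblast lists also lay inside it under several other alternatives.

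**Figure D2:**
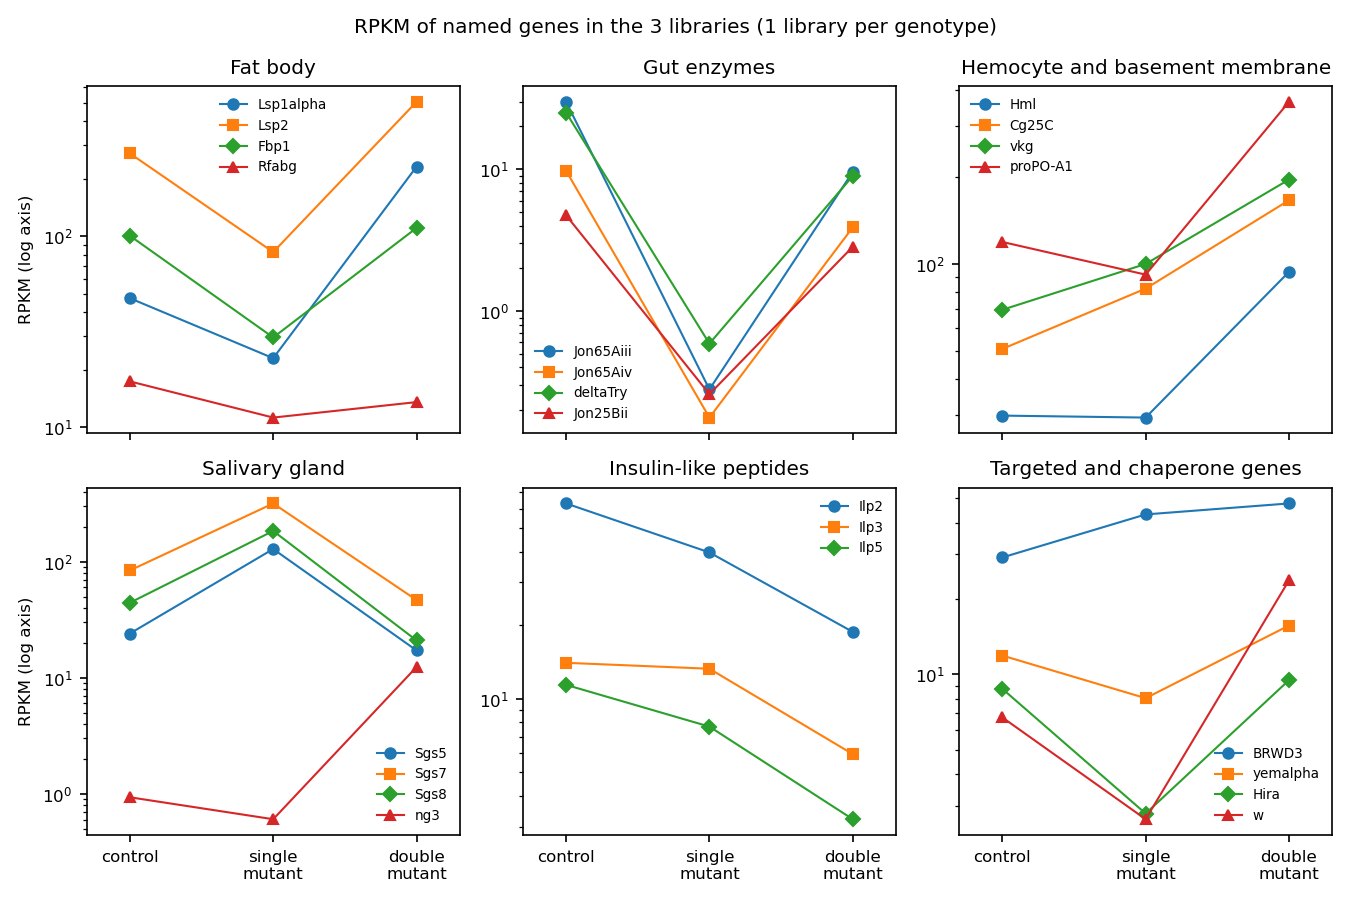
RPKM (log axis, a separate range in each panel) of named genes in the control, single mutant and double mutant libraries. Each point is 1 value of a deposited column, and lines join the points of a gene. Jon65Aiii goes from 29.9 to 0.280 and 9.57 RPKM, and Sgs7 from 84.0 to 317 and 46.7 RPKM.

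Between the library labelled double mutant and control, basement membrane and hemocyte genes and ecdysone response genes were higher, and heat shock genes and several larval cuticle and insulin-like peptide genes were lower. In the double mutant library 297 genes were at least 2-fold higher and 157 at least 2-fold lower than in control, or 508 and 94 under the rescaling without short RNA genes, where the median ratio was 0.29 in place of 0.07. With rows of no gene name included, the excess turned to 541 higher and 580 lower. CG41503 had 0.323 RPKM in control and 57.5 in the double mutant library, CG11697 had 0.192 and 32.4, CG1208,glob3 had 0.165 and 11.7, Cyp4p2 had 0.107 and 10.5 and Acp98AB was listed at 0 and had 7.54. The tubulin gene alphaTub85E had 8.202 RPKM in control, 43.1 in the single mutant and 74.8 in the double mutant library. The 6 lowest were Lcp4 (73.7 and 2.77 RPKM), CG18607 (15.6 and 0.0524), CG42500 (28.4 and 1.01), and Sfp33A4 (10.6), CG10474 (7.91) and CG34212 (7.44), which were listed at 0 in the double mutant library.

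Of 15 hemocyte and basement membrane genes 11 were at least 2-fold higher in the library labelled double mutant than in control and 0 lower, with a median of 1.24, above all 10000 random lists. The collagen IV gene Cg25C had 50.9 and 167 RPKM, srp had 2.49 and 10.3, Hml had 29.9 and 94.1 and proPO-A1 had 119 and 365. nimC1, a phagocyte receptor gene, had 7.94 and 4.15 RPKM. Fat body genes had a median of 0.46 (percentile 99.8), with 3 of 10 at least 2-fold higher (Lsp1alpha at 47.3 and 231 RPKM, Lsp1gamma at 34.7 and 123 and Lsp1beta at 64.3 and 145), and gut enzyme genes a median of -0.62 (percentile 0.01), with 4 of 10 at least 2-fold lower and Amy-p higher (0.135 and 1.73 RPKM). Both lists lay inside the random range with no filter. Muscle genes had a median of -0.24 (percentile 0.06), with Mhc at 7.99 and 2.96 RPKM and Mlp60A at 7.77 and 3.08. Eye disc genes had a median of 0.51 (percentile 99.8) and imaginal disc genes 0.42 (percentile 98.7), both inside the random range with a pseudocount of 5 RPKM and the latter also with no filter and with a filter at 5 RPKM, and dac, the most different eye disc gene, had 22.5 and 44.9 RPKM.

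Ecdysone response genes were higher in the library labelled double mutant than in control in 18 of 21 cases, 5 of them at least 2-fold, with a median of 0.64, above all random lists. CG3600,CG42527 had 0.317 and 3.32 RPKM, the nuclear receptor gene Eip75B had 10.8 and 30.1, br,dor had 13.95 and 32.9 and Eip93F had 2.90 and 7.49. Of 43 cuticle protein genes 10 were at least 2-fold lower and 5 higher, with a median of -0.40, below all random lists but inside the random range with no filter. The largest ratios were those of Lcp4, Lcp65Ab2 (14.9 and 0.942 RPKM), Lcp3 (11.4 and 1.22) and Lcp1 (13.02 and 1.75). Heat shock genes were lower in 15 of 18 cases, with a median of -0.44 (percentile 0.03), led by Hsp68 (673 and 254 RPKM) and Hsp70Bc (666 and 285), and the near-identical Hsp70 copies share reads. Glycolysis genes were lower in 13 of 15 cases with a median of -0.30 (percentile 0.01), and Pgk had 261 and 175 RPKM.

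The transmitter and neuropeptide list had a median of -0.25 between the library labelled double mutant and control, below all random lists, and its 3 members at least 2-fold lower were the insulin-like peptide genes Ilp2 (63.0 and 18.8 RPKM), Ilp5 (11.4 and 3.22) and Ilp3 (14.04 and 5.94). Ilp6 (1.12 and 1.85 RPKM) and Ilp7 (1.46 and 2.58) were higher. The neuronal function list had 17 of 19 genes higher and a median of 0.40 (percentile 99.7), and the neuroblast list a median of 0.31 (percentile 98.2). Both lay inside the random range after correction for transcript length, at 0.15 (percentile 78.3) and 0.12 (percentile 71.8), the neuroblast list also with no filter and with a pseudocount of 0.1 RPKM. Apoptosis and stress kinase genes had a median of 0.37 (percentile 99.0) with 13 of 14 higher and none at 2-fold. Cell cycle genes had a median of -0.17, below all random lists, which turned to 0.06 under the rescaling and stayed below the median of all genes there (percentile 0.01). The chemosensory (0.30), cytochrome P450 (-0.06) and antimicrobial (-0.16) lists had percentiles of 99.4, 1.84 and 2.17, and each lay inside the random range under several alternatives.

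Each gene's pattern across the 3 libraries was compared with shuffles of its values among them. The library labelled single mutant stood apart from both others in 179 genes, 36 in which it was higher (54.3 in the shuffles, central 95% 42 to 65.0) and 143 in which it was lower (68.9, 56 to 82). Genes lower in the single mutant library alone included, chosen here after their values were seen, Elp3 of the Elongator complex (32.5, 3.82 and 33.3 RPKM in control, single and double mutant), Elp2 (18.1, 4.09 and 15.2), clathrin heavy chain Chc (150, 50.1 and 175), Rab14 (5.89, 0.594 and 8.995) and the chromatin genes Iswi (54.3, 17.96 and 52.3) and ash1 (8.26, 1.85 and 9.11). Control stood apart in 122 genes, 60 in which it was higher (54.7 in the shuffles) and 62 in which it was lower (68.6). With rows of no gene name included, control stood apart in 374 and the single mutant library in 256, so which of these was larger depended on those rows. The double mutant stood apart in 76 genes, 59 higher (54.0) and 17 lower (68.4). Small RNA rows, whose ratios are uncertain, were kept in all these counts and make up several of the 17. Genes lower in control than in both mutants included the hemocyte gene He (15.1, 40.4 and 38.6 RPKM), lectin-28C (26.7, 124 and 119) and calmodulin, Cam (37.4, 83.5 and 76.8).

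**Figure D3:**
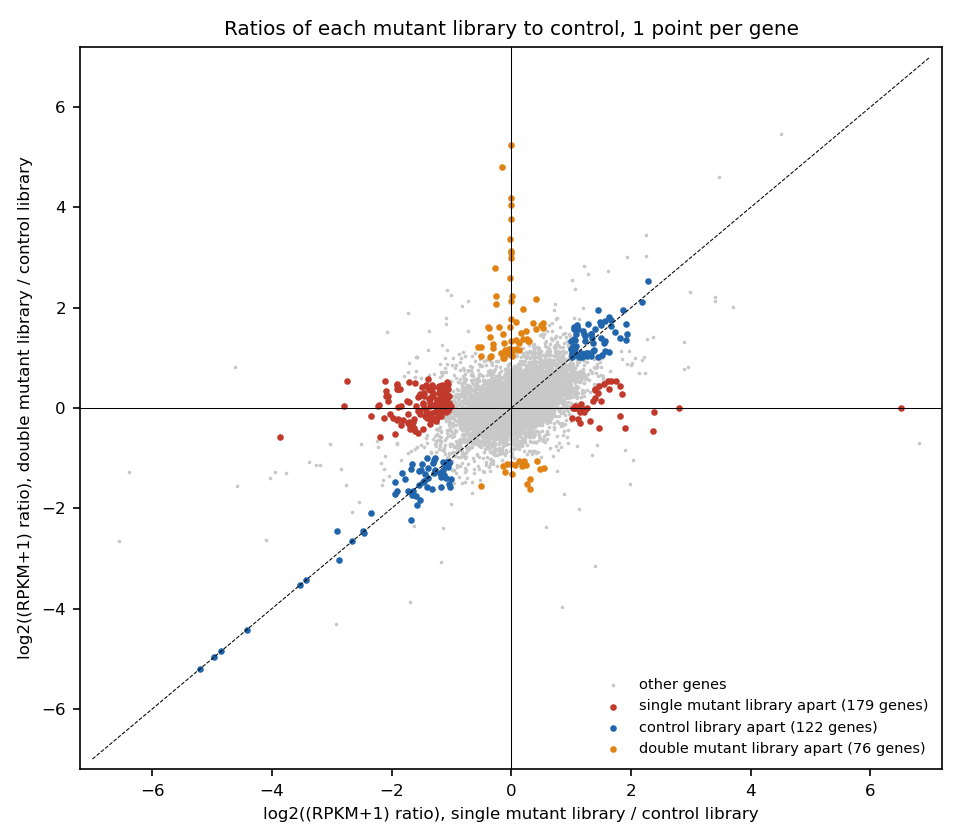
Ratio of the single mutant library (x axis) and of the double mutant library (y axis) to control for 9693 genes, as log2 of RPKM with 1 added, 1 point per gene. Coloured points are genes in which the single mutant (179), control (122) or double mutant library (76) stood apart, and the dashed line marks equal ratios.

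Of the 611 genes at least 2-fold different between the libraries labelled single mutant and control, 349 had a double mutant value nearer to control than to the single mutant, a share of 57.1% (95% exact binomial interval 53.1 to 61.1%, counting error only), against 50.1% in the shuffles (central 95% 45.8 to 54.5%). The share nearer control was uneven by direction. A single mutant library that stood apart for any reason, its preparation or noise included, would also raise this share. The share alone therefore does not show a return toward control. Of the 349 genes lower in the single mutant library, 68.2% (63.0 to 73.1%) lay nearer control, against 55.7% (50.4 to 61.2%) in the shuffles, and 53.01% lay within 1.5-fold of control. Of the 262 genes higher in the single mutant library, 42.4% (36.3 to 48.6%) lay nearer control, against 44.4% (39.3 to 49.8%) in the shuffles. The share over both directions was 44.8% when a return meant lying within 1.5-fold of control, and 41.9% when rows with no gene name were included. No shuffled level was computed for a return within 1.5-fold or with those rows, so these shares cannot be set against 50.1%.

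The ratios of the 2 mutant libraries to control, which share the control library, had a Pearson correlation of 0.48 across genes (Spearman 0.47), against 0.50 in the shuffles, and a covariance of 0.139 against 0.151. Genes are not independent replicates, and the comparisons cannot be separated from their shared library with 1 control. In both mutant libraries 85 genes were at least 2-fold higher than in control and 87 at least 2-fold lower, against 95.8 and 80.3 in the shuffles and 8.03 and 5.65 for independent lists. The shuffles keep real differences as well as noise, so values near the shuffled level do not show that shared change is absent. The ratios that share the single mutant library correlated at -0.63 (Spearman -0.57; shuffles -0.50), with a covariance of -0.203 against -0.150, and those that share the double mutant library at 0.38 (Spearman 0.35; shuffles 0.50), with a covariance of 0.105 against 0.149. With rows of no gene name included, the correlation that shares control was 0.74 and the one that shares the single mutant library -0.35, so which library stood out in these values depended on those rows.

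Genes that differed were spread over the chromosomes. Between the single mutant and control libraries, the share at least 2-fold different was 6.64% of 1747 genes on 2L, 6.16% of 1979 on 2R, 6.83% of 1902 on 3L, 6.08% of 2319 on 3R and 5.94% of 1615 on X. Within 1 Mb of BRWD3 it was 4.56% of 241 genes (95% interval 2.3 to 8.02%). On chromosome 4, 2.53% of 79 genes differed between these libraries. Their median log2 ratio was 0.29, against 0.02 on 3L (the lowest of the arms above) and 0.07 on X (the highest). Between the double and single mutant libraries the chromosome 4 median was -0.21. Within 1 Mb of yemalpha, 5.23% of 172 genes (2.42 to 9.70%) differed between the double and single mutant libraries, against 5.26% on 3R. Between the double mutant and control libraries, 70 genes on X were at least 2-fold higher and 15 lower. On 3R 63 were higher and 22 lower, and on 3L 47 and 47. The X median log2 ratio was 0.15 in that comparison, against 0.03 (2R) to 0.07 (2L) on the other chromosomes. On 2R, the rows CG10476, CG18606, CG10474 and CG18607 (15172055 to 15177305) had 3.04, 1.40, 7.91 and 15.6 RPKM in control and 7.86, 3.07, 22.4 and 28.7 in the single mutant library. In the double mutant library 3 of them were listed at 0 and CG18607 had 0.0524 RPKM. The neighbours CG11906 (13.9, 13.3 and 13.7 RPKM in control, single and double mutant) and FK506-bp2 (521, 637 and 576) differed little. RNA values alone cannot tell a loss of expression of these 4 rows from a difference in the DNA of the animals, which was not tested.

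**Figure D4:**
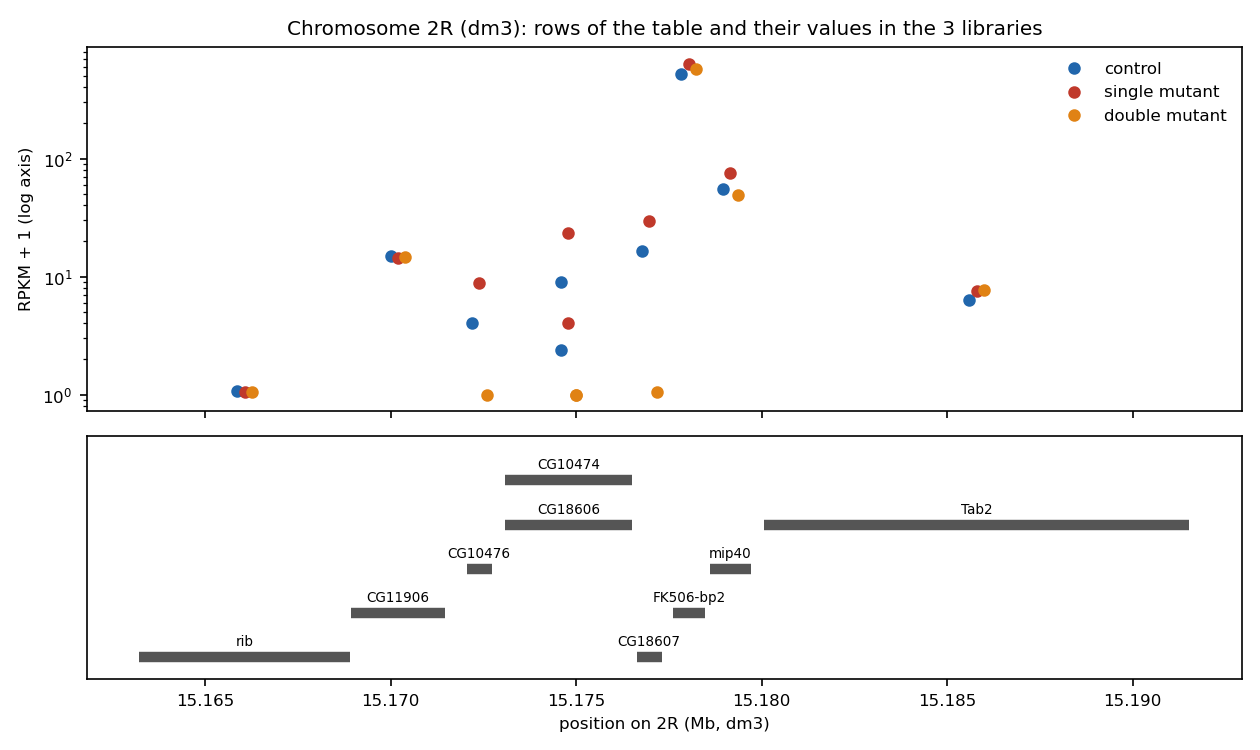
Rows of the table on 2R around CG10474 in dm3 coordinates. The upper panel gives RPKM with 1 added (log axis) in each library, drawn side by side at the middle of each row, and the lower panel the extent of each row. The 4 rows from CG10476 to CG18607 lie at or near 0 RPKM in the double mutant library alone.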

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

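Rows of the table that named no gene gave 26 loci listed at 0 in control and at 1 RPKM or more in the library labelled single mutant, and 39 loci listed at 0 in control and at 1 RPKM or more in the library labelled double mutant. They are mentioned because they carry a signal above control in data that the comparisons left out. Of these, 24 were above that level in both mutant libraries. In the other direction, 159 unnamed rows at 1 RPKM or more in control were listed at 0 in the single mutant and 149 in the double mutant library. The zeros were therefore more frequent in each mutant column than in control, whose column may hold averages of more than 1 value, for which no test was run beyond the digit counts given with the processing, and the share of genes nearer control moved to 41.9% when these rows were included.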

How the results depend on the processing

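With 1 library per genotype, counts of genes past a fold threshold depended on the processing, and so did their order. Alternatives that included rows with no gene name, left out rows or list members, or corrected for transcript length were chosen after seeing the data. For the comparisons single mutant with control, double with single mutant and double mutant with control, the main counts of 611, 557 and 454 genes became 1052, 945 and 809 with a pseudocount of 0.1 RPKM, 222, 235 and 166 with 5 RPKM, 1250, 1008 and 1121 with rows of no gene name, 1951, 1690 and 1562 at 1.5-fold, and 83, 91 and 62 at 4-fold. Under rescaling without short and multicopy RNA genes they were 563, 700 and 602, so the first comparison went from the largest count to the smallest. Host genes of small RNAs stayed in the rescaled total, so changes under this rescaling may rest on their rows, which was not tested. Genes in which control, the single mutant and the double mutant library stood apart (122, 179 and 76) became about 2.1e+02, 282 and 129 with a pseudocount of 0.1 RPKM, 37, 69 and 33 with 5 RPKM, 547, 671 and 394 at 1.5-fold, and 14, 15 and 15 at 4-fold, and 374, 256 and 169 with rows of no gene name, where control and not the single mutant had the most. The count of genes lower in the single mutant library alone (143) became 220, 49, 433 and 11 with pseudocounts of 0.1 and 5 RPKM and thresholds of 1.5-fold and 4-fold. Larger pseudocounts and thresholds call fewer genes by construction. The share nearer control (57.1%) was 41.9% with rows of no gene name and 44.8% with the stricter definition, and no shuffled level was computed for either. The correlations of 0.48 and -0.63 became 0.74 and -0.35 with rows of no gene name. The cause was not tested. The other 112 of 149 alternative values for counts, the share and correlations stayed within their tolerance. Under the same rescaling, which moved the median ratio of all genes to 0.29 between the double mutant and control libraries, 4 list medians outside the random range changed sign while staying below that range. They were the cell cycle (0.0622), antimicrobial (0.00556) and cytochrome P450 (0.0902) medians against control and the apoptosis median against the single mutant library (0.0313). The chemosensory median of the latter comparison changed sign as well (0.13) and lay inside the range (percentile 3.38), as did medians of lists inside it from the start. The share of higher genes went from 74.3% to 90.9% (double against single mutant) and from 65.4% to 84.4% (double mutant against control) there, whereas the latter was 48.3% with rows of no gene name and 56.9% with upper-quartile scaling. For the single mutant against control it went from 42.9% to 53% at 1.5-fold, 35.5% with rows of no gene name and 33.7% with upper-quartile scaling. Of 1737 alternative ratios of named genes none changed sign past 2-fold and 125 moved by 1.5-fold or more, all under another pseudocount. Depth limits genes of few RPKM, and with no replicates the variation between preparations is unknown.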

Other observations

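Some genes outside the lists described are given here, chosen after their values were seen. Copies of Stellate, a repeated gene family of the X chromosome, were listed at low values that were mostly higher in each mutant library than in control, for example 0.281, 0.976 and 3.01 RPKM in control, single and double mutant for the joined row Ste:CG33238,Ste:CG33243,Ste:CG33247, and 0.0653, 0.275 and 1.75 for Ste12DOR. These copies share reads. Of the nimB genes, nimB5 had 6.66, 15.0 and 39.0 RPKM, nimB4 had 43.8, 81.7 and 109 and nimB2 had 11.4, 15.0 and 28.7, whereas nimB1 had 27.9, 46.5 and 38.3 and nimB3 had 1.81, 1.43 and 7.64. The dosage compensation RNAs roX1 (46.2, 63.7 and 66.7 RPKM) and roX2 (367, 264 and 312) lay within 2-fold. Ribosomal protein genes (82 measured) had medians of 0.21 between single mutant and control and -0.27 between double and single mutant, both inside the range of random lists of equal expression, and Polycomb and trithorax group genes medians of 0.02 and 0.20, likewise inside.

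The tests of patterns below were chosen after the patterns were seen. Those of transcript length were fixed before their outcome was seen, and those of overlapping rows, expression level and other tissues after. Genes lower in the library labelled single mutant alone numbered 143, against an upper bound of 82 in the shuffles. After correction for transcript length 146 of 9064 genes had this pattern, 127 of them shared with the 136 before correction, so a length trend does not account for it. At a mean of 20 RPKM or more there were 43 such genes against an upper bound of 34, which argues against scatter of genes with few reads as the whole cause. Of the 143, 79 overlapped no other row, and 2 of the other 64 overlapped a row at least 2-fold higher in that library, which argues against reads given to an overlapping row as the whole cause. What stays open is whether the genotype, the single preparation or more noise in that library accounts for it, since with 1 library each these were not separated by any test and the shuffles take the libraries as equally noisy.

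The neuronal function list was higher in the library labelled double mutant than in control, with a median of 0.40 (percentile 99.5 over the 17 members with a transcript length). After correction for transcript length the median was 0.15 and the percentile 78.3, so the shift of these long genes is consistent with a general length trend between the libraries, and RNA quality or fragment size may be its source as well as biology. Neither was measured. The hypothesis that neuronal genes as a group differ beyond other genes of their length was not borne out here.

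Larval serum protein and fat body protein genes (Lsp and Fbp) were lowest in the library labelled single mutant and highest in the double mutant library. Between the single mutant and control libraries, 2 of 3 other lists of non-brain tissue (hemocyte at 0.49 and salivary gland at 0.39) lay above the random range. The fat body list (-0.97) lay below it, together with the gut enzyme list (-1.38). The salivary gland list had 5 genes higher and 5 lower, and lay inside the range with no filter and with a pseudocount of 5 RPKM. Of 15 hemocyte and basement membrane genes 11 were higher, although Hml hardly differed (29.9 and 29.4 RPKM). These lists argue only weakly against a change in the share of all non-brain tissue together. A different amount of fat body alone, or of fat body and gut, may still contribute. The 6 Lsp and Fbp genes had a median log2 ratio of 2.42 between double and single mutant libraries, and the only 2 other fat body genes above 5 RPKM in control, Rfabg and Mtp, had 0.23, but 2 genes are too few and their level in the brain itself is unknown. Carry-over of fat body and a change in expression cannot be told apart here, and differences of larval age, which also move storage, glue and ecdysone genes, are an untested biological alternative.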
